A study of Mus musculus with 16 samples.

How the data were processed

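RNA of 16 libraries was analysed, 4 replicates of each of 4 pools of CD15-positive cells from embryonic mouse dorsal telencephalon, sorted for mCherry from 1 allele of Neurog2 and GFP from 1 allele of Ascl1. The pools were taken from the sample titles. RNA was isolated with Trizol LS, libraries were made with a TruSeq stranded mRNA kit and both ends of fragments were read over 125 bases, per the labels' protocols. The growth protocol speaks only of GFP-positive cells being isolated, while the titles and descriptions name all 4 pools, and the titles were followed. The labels do not say whether the GFP allele still makes Ascl1 RNA.

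Estimated counts per gene and per transcript were deposited by the authors, and the submitters' processing notes name Trimmomatic 0.36, kallisto 0.44.0, edgeR 3.22.5 and genome GRCm38.p6 without giving the step of each. The deposited normalized table, called CPM by its name, was treated as a signal because, as deposited, each library is its estimated count divided by 1 constant, with a relative spread of at most 1.5e-09. The constants correlated at 0.972 with the TMM (trimmed mean of M values) factors computed here. The gene table held 52143 genes and 136550 transcripts were in the file by transcript, with no column of other samples. The transcript counts served only to check totals, which were the same per library, while the medians of the difference between gene count and transcript sum were 2.91% to 4.43%. Of the genes, 51336 were found in GENCODE M21, 50426 of these with the same start and end, and 857 lay on patches or alternative haplotypes, which share reads with the main chromosomes. The strand setting of the quantification is not stated, so antisense genes (Dlx6os1 and Six3os1) can hold reads of the opposite strand. Coordinates are those deposited for GRCm38.

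Counts were rounded and genes of low count were removed with filterByExpr, leaving 18091 genes. Libraries were scaled by TMM, whose factors averaged 1.02 in the double-negative, 0.975 in the Neurog2-single, 1.05 in the Ascl1-single and 0.957 in the double-positive pool. All 16 libraries were fitted together by edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with robust quasi-likelihood and 1 mean per pool, at a common biological coefficient of variation of 0.248 and 12 residual degrees of freedom. The 6 comparisons of pools and the interaction, the double-positive minus Neurog2-single difference minus the Ascl1-single minus double-negative difference, were tested, and p-values were adjusted by Benjamini-Hochberg over genes within each, at 0.05. CPM in the text is the count over the TMM-scaled library size. Group values are means ± SD and differences are log2 fold changes ± SE.

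Gene lists were written from general knowledge: radial glia, intermediate progenitors, cortical glutamatergic neurons, pan-neuronal, Cajal-Retzius neurons, GABAergic and ventral telencephalic, oligodendrocyte lineage, Notch pathway, Neurog2 targets, Ascl1 targets, S phase, G2 and M phase, cell cycle exit, cortical area and dorsal patterning, cortical hem with roof plate and choroid plexus, human outer radial glia, cortical folding regulators, erythroid, endothelial, microglia, mesenchyme, surface ectoderm, immediate early, heat shock, mitochondrially encoded and embryo sex. Some genes are in more than 1 list, and members with too few counts were not tested (Lhx6, Npy and Sst of the GABAergic list, for example). The folding list holds Adgrg1 under its present name, and its old name was not found. Lists were tested with camera, with a preset correlation of 0.01 between genes and p-values adjusted over lists within each comparison. Camera was repeated with an estimated correlation, and otherwise only with the replicate number as a block, library size alone or each library left out. The latter are the other alternatives given for list calls. List levels are the mean log2 CPM of tested members with a prior count of 2, compared by exact permutation of 4 against 4 libraries, whose smallest two-sided p is 0.0286, with adjustment over the 6 comparisons.

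Genes were named by a rule. Neurog2, Ascl1 and Fut4 were given in every pool. In each comparison the 6 genes furthest up and the 6 furthest down were named among those called, with a mean of at least 5 CPM over the 16 libraries and no overlap between the libraries of the 2 pools, predicted genes left out. For the interaction the 4 genes with the smallest adjusted p on each side were named. From each list, up to 4 members with the smallest adjusted p and members that moved against the majority were named. Other genes named for a list were chosen after their values were seen. Except as follows, the pools, comparisons, main tests, lists, naming rule and alternatives were fixed before the data were examined. The setting that joins the replicate number as a block with an estimated correlation between list members was not planned. Nor were tests of list levels outside the radial glia, intermediate progenitor, glutamatergic, GABAergic, Notch, S phase and G2 and M phase lists.

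Whether equal replicate numbers pair libraries of different pools was checked by the correlation of their deviations from the pool means, with pairing taken where each correlation exceeded 0.1. The correlations were 0.31 to 0.40 for the Neurog2-single and double-negative pools, 0.25 to 0.35 for the Ascl1-single and double-negative pools, 0.11 to 0.31 for the double-positive and Ascl1-single pools, and 0.28 to 0.36 for the Ascl1-single and Neurog2-single pools. The numbers were therefore taken to pair these, from the data and not from the labels. The main fit still took libraries as unpaired. In these comparisons, in the same order, it called 6519, 4351, 5784 and 4945 genes. With the replicate number as a block edgeR called 7568, 5415, 6839 and 6065. The alternatives tried were the replicate number as a block, DESeq2 1.42.0, edgeR with size factors of the DESeq2 type, scaling by library size alone, no filter, a filter of at least 1 CPM in 4 libraries, only the libraries of the 2 pools compared, limma-trend on log2 of the deposited CPM, each library left out in turn, an estimated correlation between list members, the median over members, and control libraries split 2 and 2.

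The tests were tried on simulated counts with changed genes (68, 58 and 74 at 1.5-fold, 2-fold and 4-fold for the Neurog2-single and double-negative pools, and 72, 62 and 66 for the interaction). For the Neurog2-single and double-negative pools edgeR recovered 13.2%, 56.9% and 74.3% of genes changed 1.5-fold, 2-fold and 4-fold with 2 false calls among 18091 genes, DESeq2 recovered 25%, 67.2% and 83.8% with 25 false calls, and limma-trend 13.2%, 56.9% and 79.7% with 3. For the interaction edgeR recovered 1.39%, 32.3% and 65.2% with 4 false calls. A raised list of 20 genes had a camera adjusted p of 5.13e-51, and of 100 random lists none was called (edgeR counts, camera). The simulated genes were drawn independently, so this does not show how camera behaves on lists whose members vary together. Changes of 4-fold were therefore missed in part too, and a gene not called is not shown to be equal between pools. Transcript use was not analysed here.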

Results

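Polyadenylated RNA was profiled in cells of mouse embryonic dorsal telencephalon, the tissue that forms the cerebral cortex. The embryos carried a Flag-tagged mCherry at 1 allele of Neurog2 and GFP at 1 allele of Ascl1. Both genes encode basic helix-loop-helix transcription factors that start neuron production. Neurog2 is known for glutamatergic neurons of the dorsal telencephalon, and Ascl1 for GABAergic neurons of the ventral telencephalon. Cells bearing CD15, a surface carbohydrate of neural progenitors, were sorted by the reporters into a double-negative, a Neurog2-single, an Ascl1-single and a double-positive pool, with 4 replicates each. The labels' fields disagree on the embryonic age (day 11.5 in the sample characteristics, later days in the titles, design and growth protocol), so the stage is uncertain. The 16 libraries held 19854725 to 26196870 estimated counts, and 21436 genes (double-positive replicate 2) to 25753 genes had at least 1 count. The labels do not say whether replicates came from separate embryos or litters, so p-values measure only the spread between these samples. Over the 1000 most variable genes, the first principal component held 42.9% and the second 17.4% of the variance. On the first, the Neurog2-single and double-positive libraries lay at 27 to 44.3 and the other pools at -46.7 to -23.5. On the second, the Ascl1-single libraries lay at -45.6 to -25.2 and the double-negative libraries at 22.7 to 33.3.

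The genes of the sort followed the pool names. Neurog2 (ENSMUSG00000027967, GRCm38 chromosome 3, 127633135 to 127635631) stood at 105 ± 14.1 CPM (counts scaled by library size, mean ± SD, n = 4) in the double-negative, 291 ± 30.6 in the Neurog2-single, 117 ± 47.4 in the Ascl1-single and 391 ± 58.2 in the double-positive pool. Ascl1 (ENSMUSG00000020052, chromosome 10, 87490819 to 87493660) stood at 23.7 ± 4.65, 24.1 ± 4.89, 271 ± 119 and 70.7 ± 15.3 CPM in the same order. Ascl1 RNA in the double-positive pool was therefore above that of the pools without GFP and, by a log2 difference of -1.94 ± 0.27 (SE), below that of the Ascl1-single pool. Within the Ascl1-single pool, replicates 1 and 2 held 342 and 402 CPM of Ascl1, and replicates 3 and 4 held 179 and 162 CPM. Fut4 (ENSMUSG00000049307, chromosome 9, 14748320 to 14752393), which encodes an enzyme that makes CD15, was low throughout, at 1.11 ± 0.187, 0.431 ± 0.153, 0.286 ± 0.173 and 0.726 ± 0.381 CPM, so its differences rest on few counts. Neurog2 and Ascl1 were used to choose the cells, so their differences check the labels and are not findings.

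**Figure D1:**
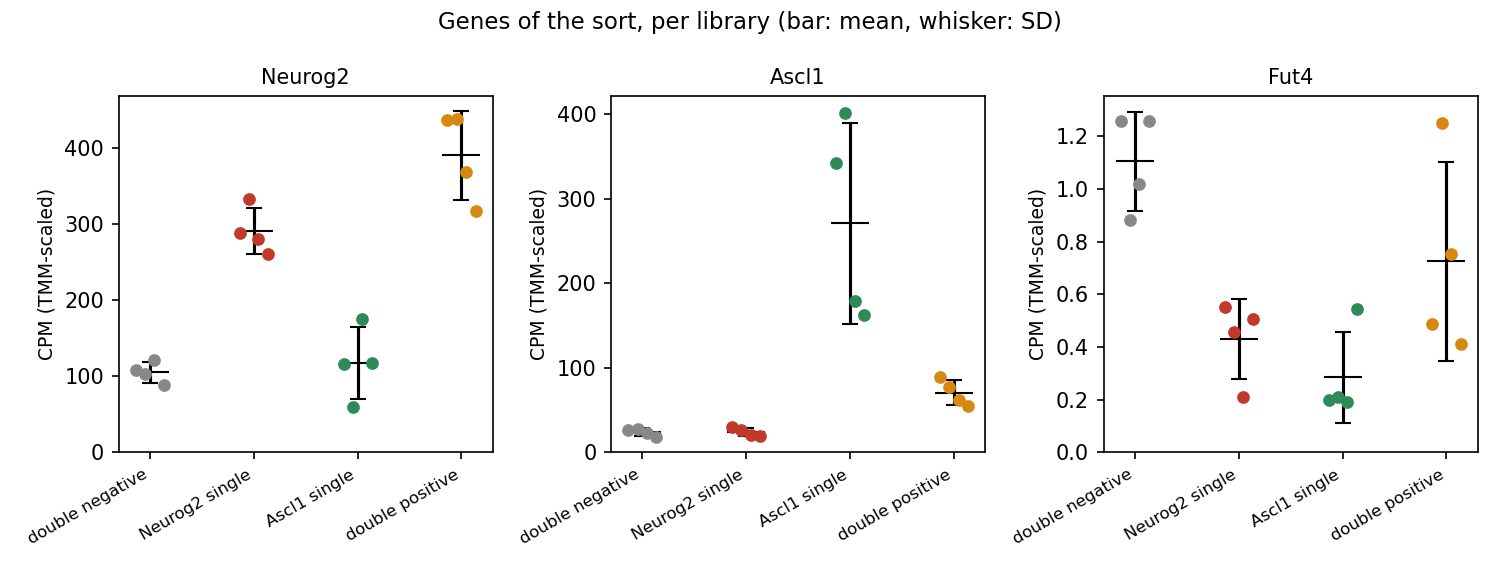
CPM of Neurog2, Ascl1 and Fut4 in each of the 16 libraries, by pool, with points for libraries, bars for means and whiskers for SD. Neurog2 averaged 291 and 391 CPM in the mCherry-positive pools against 105 and 117 CPM in the others, and Ascl1 averaged 271 CPM in the Ascl1-single pool against 70.7 CPM in the double-positive pool.

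The sort forms a 2 by 2 layout of the markers, so each pair of pools was compared and the interaction of the markers was tested. Differences below are log2 fold changes ± SE of the first-named pool over the second, from edgeR's quasi-likelihood test on 18091 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Unless a list is named, genes were taken for the size of their change among those called, and their 4 libraries in 1 pool did not overlap the 4 in the other. Chance alone gives no overlap in 2 of 70 arrangements of 8 libraries. Against the double-negative pool, 6519 genes were called in the Neurog2-single, 4351 in the Ascl1-single and 7532 in the double-positive pool. The Ascl1-single and Neurog2-single pools differed in 4945 genes, the double-positive and Ascl1-single pools in 5784, and the double-positive and Neurog2-single pools in 603.

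**Figure D2:**
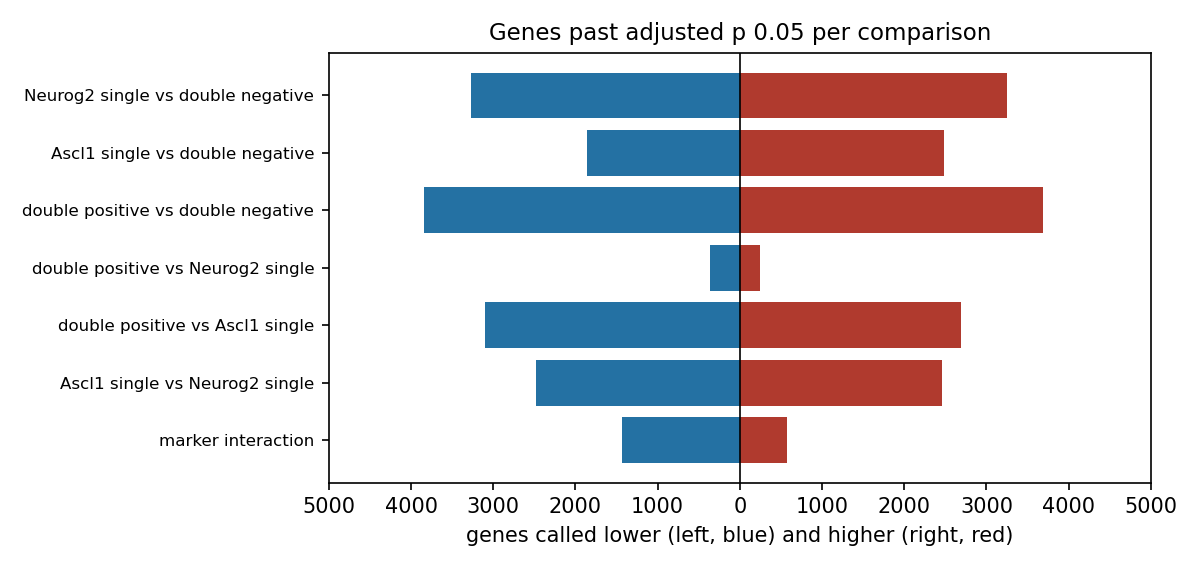
Genes past an adjusted p of 0.05 in each of the 6 comparisons and the marker interaction, lower to the left in blue and higher to the right in red, by edgeR's quasi-likelihood test. The fewest calls, 245 higher and 358 lower, were between the double-positive and Neurog2-single pools, and the most, 3692 and 3840, between the double-positive and double-negative pools.

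Between the Neurog2-single and double-negative pools, which differ in mCherry, neurogenic genes were higher and radial glial genes lower with mCherry. Intermediate progenitor genes rose in 18 of 19 tested, among them Nhlh1, a neuronal differentiation factor (7.31 ± 0.26), and Sstr2, a somatostatin receptor (6.82 ± 0.25). Eomes, the defining factor of cortical intermediate progenitors, averaged 25.6 CPM in the double-negative and 1155 CPM in the Neurog2-single pool. Cortical glutamatergic neuron genes rose in 16 of 22, led by the transcription factors Neurod6 (7.75 ± 0.21), Neurod2 (6.67 ± 0.22) and Neurod1 (6.52 ± 0.21), and fell in 2, Lmo3 (-2.04 ± 0.41) and Tle4 (-0.37 ± 0.13). All 20 pan-neuronal genes rose, among them the neuronal tubulin gene Tubb3 (3.68 ± 0.17) and Rbfox3, which encodes the neuronal antigen NeuN (6.20 ± 0.28). Cajal-Retzius neuron genes, markers of the earliest cortical neurons, rose in 11 of 15, with Ebf2 at 6.66 ± 0.33 and Reln at 4.02 ± 0.36, and Emx2 fell (-0.89 ± 0.11). Radial glial genes fell in 18 of 20, among them the progenitor transcription factors Sox9 (-1.51 ± 0.14) and Pax6 (-1.20 ± 0.13) and the neuronal gene repressor Rest (-1.54 ± 0.17). All 17 genes of a list of known Neurog2 targets rose, a list that shares Neurod1, Neurod2, Neurod6 and Nhlh1 with those above. The level of the Ascl1 target list was higher too, by 1.3 (exact permutation p = 0.0286, adjusted 0.0343).

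Cell cycle and signalling genes also differed between the Neurog2-single and double-negative pools. S phase genes fell in 20 of 25, such as the replication licensing gene Cdc6 (-0.94 ± 0.11) and the histone mRNA binding gene Slbp (-0.85 ± 0.09), while the cell cycle factor E2f1 rose (0.88 ± 0.11). Cell cycle exit genes rose in 9 of 11, such as Gadd45g (3.82 ± 0.16) and Btg2 (1.68 ± 0.11). Of the 25 Notch pathway genes 9 rose, such as the ligand gene Dll1 (3.08 ± 0.15) and Mfng (3.18 ± 0.13), and 7 fell, such as the effector Hes1 (-2.15 ± 0.31) and the receptor Notch2 (-1.59 ± 0.17). Cortical hem, roof plate and choroid plexus genes fell in 12 of 20, with Wnt8b at -1.67 ± 0.26. Erythroid genes rose in 10 of 12, such as the heme synthesis gene Alas2 (3.59 ± 0.43) and the embryonic globin Hbb-bh1 (4.54 ± 0.92), and took 0.404% to 1.11% of the counts of each Neurog2-single library against at most 0.0576% in every other library. By size, the genes furthest up were Xkr7 (7.92 ± 0.47), Neurod6, the somatostatin receptor gene Sstr3 (7.74 ± 0.47), Serpinb2 (7.55 ± 0.55), Clvs1 (7.46 ± 0.49) and Nhlh1. Xkr7, Sstr3 and Serpinb2 averaged 0.0776, 0.0798 and 0.0405 CPM in the double-negative pool, so their folds rest on few counts there. Furthest down were Gsx2, the growth factor gene Fgf17 (-3.70 ± 0.38), Six3os1, Wnt9a, Galnt12 and Lrrc23. Gsx2, a ventral telencephalic factor, had no count in any Neurog2-single library and was at least 12.3-fold higher in the double-negative pool, against a floor of 3 counts over the group.

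In total 3249 genes were higher and 3270 lower in the Neurog2-single than in the double-negative pool by edgeR's quasi-likelihood test, 1572 and 1140 of them by at least 2-fold, and 5577 showed no overlap between libraries. With scaling by library size alone the split was 2860 higher and 3842 lower. Adjusted over the list alone, the counts above were the same except S phase (22 lower) and Notch (10 higher, 8 lower). By camera, a competitive gene set test, the intermediate progenitor list had adjusted p = 1.34e-72 and the radial glia list 6.70e-12, and these and the glutamatergic, pan-neuronal, Cajal-Retzius, Neurog2 target and cell cycle exit calls held with an estimated correlation between genes. The S phase call (adjusted p = 0.188 with an estimated correlation, 2.25e-11 to 4.11e-08 over the other alternatives), the Notch call (0.149, others 0.000788 to 0.0103), the hem call (0.331, others 2.82e-05 to 0.000705) and the erythroid call (0.392, others 0.000357 to 0.00249) did not. The call of Gsx2 was lost with limma-trend on the deposited CPM (adjusted p = 0.0921).

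Between the Ascl1-single and double-negative pools, which differ in GFP, genes of GABAergic and ventral telencephalic cells were higher with GFP. Of 20 tested, 18 rose, among them the homeobox genes Dlx1 (7.65 ± 0.83) and Dlx2 (5.99 ± 0.50), and the GABA synthesis genes Gad1 (6.18 ± 0.60) and Gad2 (6.09 ± 0.67). The list also holds Ascl1 itself (3.51 ± 0.29), and its member Arx fell (-0.35 ± 0.12). Dlx1 averaged 1.29 ± 0.516 CPM in the double-negative and 265 ± 169 CPM in the Ascl1-single pool (SD, n = 4). Furthest up by size was Dlx6os1 (9.17 ± 0.94), which lies antisense beside Dlx6, followed by Dlx1, the LIM homeobox genes Lhx1 (7.48 ± 0.80) and Isl1 (6.53 ± 0.67), Gad1 and Gad2. Intermediate progenitor genes rose in 18 of 19, such as Hes6 (2.60 ± 0.13) and Gadd45g (3.15 ± 0.16), pan-neuronal genes in 18 of 20, such as Tubb3 (2.47 ± 0.16), and Cajal-Retzius genes in 12 of 15, such as Zic1 (2.53 ± 0.15). Cortical glutamatergic neuron genes rose in 12 of 22, with Neurod1 at 3.13 ± 0.20, and fell in 3, Ppp1r1b, Lmo3 and Nfib.

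Oligodendrocyte lineage genes rose in 5 of 13 in the Ascl1-single pool, including the lineage factors Olig2 (5.26 ± 0.38) and Olig1 (4.90 ± 0.40), and Bcan fell (-1.45 ± 0.41). All 17 Neurog2 target genes and 11 of 18 Ascl1 target genes rose, Dll1 (2.63 ± 0.15) and Hes6 being in both lists, and of the latter the cell cycle genes Skp2 (-0.48 ± 0.09) and Cdk2 (-0.56 ± 0.11) fell. S phase genes fell in 21 of 25, with Cdc6 at -1.06 ± 0.11, and cell cycle exit genes rose in 9 of 11, with the cyclin-dependent kinase inhibitor gene Cdkn1c at 5.03 ± 0.30. Among cortical area and dorsal patterning genes 5 of 20 rose and 9 fell, with Fgf17, a signal of the rostral forebrain, at 4.22 ± 0.33 and the dorsal factor Emx2 at -0.75 ± 0.11. Radial glial genes fell in 6 of 20, such as Pax6 (-0.66 ± 0.12), and Sox1 rose (0.72 ± 0.12). Furthest down by size were Rbm20 (-2.74 ± 0.55), the adhesion gene Mcam (-2.71 ± 0.48), the Notch effector Hey2 (-2.60 ± 0.42), Cav1, Tgfb2 and Fgfr3.

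In total 2488 genes were higher and 1863 lower in the Ascl1-single than in the double-negative pool by edgeR's quasi-likelihood test, 1385 and 385 of them by at least 2-fold, and 3870 showed no overlap between libraries, while library size alone gave 2748 higher and 1525 lower. The GABAergic list, adjusted over the list alone, had 19 higher, the glutamatergic list 14 higher and 4 lower, the Cajal-Retzius list 2 lower, the oligodendrocyte list 2 lower, the Ascl1 target list 3 lower, S phase 24 lower and the patterning list 7 higher. The cell cycle exit list gained 1 lower member, and the other counts given above were the same. By camera the GABAergic (adjusted p = 1.79e-21), intermediate progenitor (3.01e-49), glutamatergic, pan-neuronal, Cajal-Retzius, oligodendrocyte, target, S phase and cell cycle exit calls held with an estimated correlation, and the patterning list was not called (adjusted p = 0.710). The radial glia list was not called by camera (adjusted p = 0.0620) but was with the replicate number as a block (0.0387) and without double-negative replicate 1 (0.0488), double-negative replicate 3 (0.0494) or Ascl1-single replicate 4 (0.0473). It was not called with an estimated correlation, without the block (0.651) or with it (0.633). The list level of radial glia differed by -0.21 (exact permutation p = 0.0286, adjusted 0.0343). That exact permutation p was 0.0571 with library size alone, with the median over members and without any 1 double-negative library.

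Between the Ascl1-single and Neurog2-single pools, dorsal neurogenic genes were lower and ventral genes higher in the Ascl1-single pool. GABAergic and ventral genes were higher in 19 of 20, with Dlx1 at 9.07 ± 0.93 and Dlx2 at 7.63 ± 0.56, while Ebf1 was lower (-2.60 ± 0.36). Gsx2, at 20.6 CPM in the Ascl1-single pool, was at least 578-fold higher there against the floor of 3 counts over the Neurog2-single group, and its relative Gsx1 at least 162-fold. Dlx6os1 (8.83 ± 0.93), Nkx2-1, a factor of the medial ganglionic eminence (7.95 ± 0.87), and Fgf17 (7.92 ± 0.42) were also furthest up. Nkx2-1 had counts in 1 of the 4 Neurog2-single libraries (0.627 CPM in replicate 3), so the size of its fold rests on that library. Glutamatergic neuron genes were lower in 17 of 22, such as Neurod6 (-5.62 ± 0.19) and Slc17a7, which encodes a vesicular glutamate transporter (-5.04 ± 0.21), and higher in 3, Tle4, Lmo4 and Foxp2. Intermediate progenitor genes were lower in 16 of 19, such as Nhlh1 (-4.05 ± 0.21), and pan-neuronal genes in 18 of 20, such as Rbfox3 (-3.35 ± 0.23). Radial glial genes were higher in 14 of 20, such as Sox1 (1.86 ± 0.12), Sox9 (1.12 ± 0.14) and Sox2 (1.12 ± 0.15). Hem, roof plate and choroid plexus genes were higher in 12 of 20, with Otx2 at 3.91 ± 0.51, and the 4 higher of 7 surface ectoderm and epithelium genes included Epcam, a cell adhesion gene (3.61 ± 0.29), and Krt18 (2.80 ± 0.53). Erythroid genes were lower in 10 of 12 and filled the list of genes furthest down, from Hba-x (-6.46 ± 1.16) to Slc4a1 (-5.81 ± 1.06). The alpha globin genes Hba-a1 and Hba-a2 are near-identical, so the split of reads between them is uncertain.

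In total 2464 genes were higher and 2481 lower in the Ascl1-single than in the Neurog2-single pool by edgeR's quasi-likelihood test, 1358 and 884 of them by at least 2-fold, and 4148 showed no overlap. With scaling by library size alone the split was 3291 higher and 1789 lower. With p-values adjusted over the list alone, 17 intermediate progenitor genes were lower and 1 higher, 17 radial glial genes were higher, and the other counts given above were the same. By camera the GABAergic (adjusted p = 2.58e-22), glutamatergic, intermediate progenitor, pan-neuronal, radial glia and surface ectoderm calls held with an estimated correlation. The hem call (adjusted p = 0.0953 with an estimated correlation, 1.41e-14 to 1.30e-07 over the other alternatives) and the erythroid call (0.162, others 2.77e-08 to 2.45e-06) did not. With the replicate number as a block, the immediate early gene list was called (camera adjusted p = 0.0211, against 0.200 without), with Fosb at 1.63 ± 0.38 and Atf3 at 1.55 ± 0.42, as was cell cycle exit (0.0211, against 0.0517 without), which was also called without any 1 of Neurog2-single replicates 1 (0.0391), 3 (0.0492) and 4 (0.0231) or Ascl1-single replicates 1 (0.0142) and 2 (0.0461). With the block and an estimated correlation together neither list was called (0.344 for immediate early genes and 0.245 for cell cycle exit).

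Between the double-positive and double-negative pools, which differ in both markers, neurogenic genes were higher and radial glial genes lower with the markers. All 19 intermediate progenitor genes rose, such as Gadd45g (4.64 ± 0.17) and Mfng (3.87 ± 0.14), with Eomes averaging 1391 CPM in the double-positive pool. Glutamatergic neuron genes rose in 16 of 22, such as Neurod6 (7.21 ± 0.21) and Slc17a7 (6.34 ± 0.24), and fell in 2, Lmo3 and Foxp2. Pan-neuronal genes rose in 19 of 20, such as Tubb3 (4.02 ± 0.17), and Cajal-Retzius genes in 11 of 15, such as Lhx1 (8.13 ± 0.80) and Ebf2 (7.25 ± 0.33), while Emx2 fell (-0.87 ± 0.11). Radial glial genes fell in 18 of 20, such as Sox9 (-1.82 ± 0.14) and Ddah1 (-2.59 ± 0.23). S phase genes fell in 22 of 25, with Cdc6 at -1.90 ± 0.11, while E2f1 rose (0.98 ± 0.11), and G2 and M phase genes rose in 14 of 25, with the mitotic kinase gene Aurka at 0.93 ± 0.10 and Cdc20 at 0.87 ± 0.11. Erythroid genes were not called as a list (median -0.48, camera adjusted p = 0.649). Notch pathway genes rose in 11 of 25, such as Dll1 (3.84 ± 0.16), and fell in 8, such as Hes1 (-3.48 ± 0.34) and the ligand gene Jag1 (-2.06 ± 0.16). Of 14 genes known to regulate cortical folding in mouse models, 4 rose, such as Trnp1 (1.91 ± 0.50), and 8 fell, such as the growth factor receptor gene Fgfr2 (-2.04 ± 0.26). Furthest up by size were Serpinb2 (8.82 ± 0.55), Lhx1, Xkr7, Sstr3, Nhlh1 and Ebf2, and furthest down Ctgf (-4.43 ± 0.40) and Cyr61 (-4.26 ± 0.45), both known targets of Yap signalling, the adhesion gene Vcam1 (-4.20 ± 0.40), Pappa, Hhipl1 and Fam184b. Serpinb2, Lhx1, Xkr7 and Sstr3 averaged under 0.1 CPM in the double-negative pool, so these folds rest on few counts.

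In total 3692 genes were higher and 3840 lower in the double-positive than in the double-negative pool by edgeR's quasi-likelihood test, 1655 and 1816 of them by at least 2-fold, and 6611 showed no overlap. With scaling by library size alone the split was 3128 higher and 4623 lower. S phase had, adjusted over the list alone, 23 lower, G2 and M phase 15 higher and the folding list 5 higher, with the other counts given above the same. By camera the intermediate progenitor (adjusted p = 1.34e-72), glutamatergic, pan-neuronal, Cajal-Retzius and radial glia calls held with an estimated correlation, and the folding list was not called (adjusted p = 0.570). The calls of S phase (adjusted p = 0.0697 with an estimated correlation, 2.04e-17 to 2.79e-14 over the other alternatives), G2 and M phase (0.616, others 6.40e-05 to 0.00213) and Notch (0.115, others 0.00219 to 0.0187) did not hold, though S phase was called with the replicate block and an estimated correlation together (0.0360).

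Between the double-positive and Neurog2-single pools, which differ in GFP among mCherry-positive cells, mitotic genes were higher with GFP. G2 and M phase genes rose in 19 of 25, with Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 1.12 ± 0.14, Cdc20 at 0.95 ± 0.11, Aurka at 0.92 ± 0.10 and Plk1 at 0.88 ± 0.11. S phase genes fell in 8 of 25, with Cdc6 at -0.96 ± 0.11 and Mcm6, a replicative helicase gene, at -0.71 ± 0.13, but the call of the list was lost with an estimated correlation (camera adjusted p = 0.130). Ascl1 target genes rose in 5 of 18, such as the mitotic phosphatase gene Cdc25b (1.29 ± 0.12) and Cdk1 (0.73 ± 0.12). That list shares Cdk1 with the G2 and M phase list, and Hes6 and Gadd45g with the intermediate progenitor list. Intermediate progenitor genes rose in 6 of 19, such as Hes6 (0.99 ± 0.12), Gadd45g (0.82 ± 0.15) and Mfng (0.69 ± 0.12). Of 22 glutamatergic neuron genes Fezf2 rose (0.79 ± 0.10), and Cntn2 (-0.83 ± 0.19) and Lmo4 (-0.53 ± 0.14) fell. Of 20 pan-neuronal genes the microtubule gene Mapt (-1.10 ± 0.21) and Ncam1 (-0.68 ± 0.15) fell. Cntn2 was not called without Neurog2-single replicate 1 or 2 or double-positive replicate 1, 2 or 4 (adjusted p = 0.0504 to 0.0758 by edgeR), Lmo4 without Neurog2-single replicate 1, 2 or 3 or any 1 double-positive library (0.0704 to 0.114), and Ncam1 without Neurog2-single replicate 4 (0.0581) or double-positive replicate 2 (0.0597). GABAergic and ventral genes rose in 3 of 20, Ascl1, Six3 and Sp8 (1.24 ± 0.13), and Sp9 fell (-3.01 ± 0.78), a call lost without Neurog2-single replicate 2, 3 or 4 or any 1 double-positive library (adjusted p = 0.0824 to 0.125 by edgeR). Sp8 stood at 69.6 CPM in the double-positive and 68.6 CPM in the double-negative pool. The human outer radial glia list, of genes marking basal progenitors, was not called, and its member Ptprz1 fell (-1.53 ± 0.22). Camera called that list between the Ascl1-single and Neurog2-single pools (adjusted p = 0.00285), the double-positive and Ascl1-single pools (0.00306), and in the interaction (0.0271). With an estimated correlation each of these calls was lost (0.0898, 0.0973 and 0.2). Erythroid genes fell in 10 of 12, with Alas2 at -4.14 ± 0.45. Furthest up by size were Insm2 (2.94 ± 0.69), Six3 (2.62 ± 0.64), the serotonin receptor gene Htr3a (1.85 ± 0.31), C1qtnf1 (1.83 ± 0.36), Ptprt (1.82 ± 0.45) and Phyhip (1.77 ± 0.28). Furthest down were the transcription factor genes Shox2 (-6.14 ± 0.93) and Olig3 (-5.00 ± 0.74) and the globin genes Hba-a2 (-5.03 ± 1.06), Hbb-bh1 (-4.98 ± 0.95), Hbb-y (-4.92 ± 1.12) and Hba-a1 (-4.56 ± 1.06). Shox2 and Olig3 averaged 23.6 and 19.4 CPM in the Neurog2-single pool and 0.336 and 0.600 CPM in the double-positive pool.

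This was the smallest and least stable difference between pools. In total 245 genes were higher and 358 lower in the double-positive than in the Neurog2-single pool by edgeR's quasi-likelihood test, 65 and 181 of them by at least 2-fold, and 571 of the 603 showed no overlap, while library size alone gave 227 higher and 428 lower. The count was 1121 with DESeq2 and 381 with only the 8 libraries of these pools, and it was 373 without Neurog2-single replicate 3, 397 without Neurog2-single replicate 4, 330 without double-positive replicate 1 and 346 without double-positive replicate 2. The call of Insm2 was lost without any 1 of the 4 Neurog2-single libraries or double-positive replicate 1 or 2 (adjusted p = 0.0514 to 0.0877 by edgeR's quasi-likelihood test), as was that of Six3 (0.0582 to 0.0962), and that of Ptprt without any 1 of the 4 Neurog2-single libraries or double-positive replicate 1, 2 or 3 (0.0556 to 0.117). The calls of Hba-a1 (0.0587 to 0.108) and Hbb-y (0.0522 to 0.0905) were lost without Neurog2-single replicate 2, 3 or 4 or double-positive replicate 2 or 4, that of Hba-a2 without Neurog2-single replicate 3 or double-positive replicate 2, 3 or 4 (0.0501 to 0.0546), and that of Hbb-bh1 with only the 8 libraries of these pools (0.0633). Adjusted over the list alone, 24 G2 and M phase genes rose, 14 S phase genes fell, 8 Ascl1 target genes rose and 1 fell, 7 intermediate progenitor and 11 GABAergic genes rose, 11 erythroid genes fell, 2 glutamatergic genes rose and 6 fell, and 1 pan-neuronal gene rose and 3 fell. The level of the cell cycle exit list was also higher in the double-positive pool, by 0.41 (exact permutation p = 0.0286, adjusted 0.0343). By camera the G2 and M phase (adjusted p = 1.90e-48), Ascl1 target (8.85e-12) and erythroid calls held with an estimated correlation, and the outer radial glia list had adjusted p = 0.666. The S phase call (adjusted p = 0.130 with an estimated correlation, 1.13e-20 to 6.57e-09 over the other alternatives), the intermediate progenitor call (0.0753, others 1.67e-11 to 5.84e-08) and the GABAergic call (0.0830, others 1.81e-12 to 1.53e-07) did not. Nor did the pan-neuronal call (0.582, others 0.00127 to 0.0606, the highest without double-positive replicate 4), and the glutamatergic list was not called (0.478). Camera also called the radial glia (adjusted p = 0.0165) and Neurog2 target lists (0.0143), both lost with an estimated correlation (0.669 and 0.582).

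Between the double-positive and Ascl1-single pools, which differ in mCherry among GFP-positive cells, 19 of 20 GABAergic and ventral genes were lower with mCherry. They included Gsx2 (-7.10 ± 0.69), Nkx2-1 (-7.03 ± 0.81), Dlx2 (-5.96 ± 0.50) and Gad1 (-5.40 ± 0.57), while Ebf1 was higher (2.52 ± 0.36). All 19 intermediate progenitor genes were higher, such as Nhlh1 (4.07 ± 0.21) and the small GTPase gene Rnd2 (3.24 ± 0.19). Glutamatergic neuron genes were higher in 17 of 22, such as Neurod6 (5.08 ± 0.18) and Slc17a7 (4.58 ± 0.21), and lower in 4, Lmo3, Lmo4, Foxp2 and Tle4. Pan-neuronal genes were higher in 14 of 20, and radial glial genes lower in 15 of 20, such as Sox9 (-1.43 ± 0.14) and Sox1 (-1.24 ± 0.12). Oligodendrocyte lineage genes were lower in 7 of 13, such as Olig1 (-4.52 ± 0.39), and higher in 2, Nfia and Slc1a2. Hem, roof plate and choroid plexus genes were lower in 12 of 20, with Otx2 at -3.64 ± 0.50 and the Wnt signalling gene Rspo1 at -4.37 ± 0.47. The Hedgehog receptor gene Ptch1 (-3.26 ± 0.26) and ligand gene Shh (-3.91 ± 0.66) were lower. Also furthest up were Fam107a (4.56 ± 0.30), Serpinb2 (4.35 ± 0.38) and Elfn2 (4.02 ± 0.44), and furthest down Fgf17 (-6.50 ± 0.38), Dlx6os1 (-6.12 ± 0.76) and the chloride channel gene Ano1 (-5.71 ± 0.45).

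In total 2689 genes were higher and 3095 lower in the double-positive than in the Ascl1-single pool by edgeR's quasi-likelihood test, 807 and 1802 of them by at least 2-fold, and 4963 showed no overlap. With scaling by library size alone the split was 1749 higher and 4076 lower. Counts adjusted over the list alone were 16 pan-neuronal genes higher, 3 oligodendrocyte genes higher and 8 lower, and 15 hem genes lower, with the other counts given above the same. By camera the GABAergic (adjusted p = 1.18e-12), intermediate progenitor (6.56e-39), glutamatergic, pan-neuronal and radial glia calls held with an estimated correlation. The oligodendrocyte call (adjusted p = 0.0508 with an estimated correlation, 0.000906 to 0.0107 over the other alternatives) and the hem call (0.157, others 1.31e-11 to 8.77e-06) did not. With the replicate number as a block, the Cajal-Retzius list (camera adjusted p = 0.00880, against 0.0603 without; 0.0219 with library size alone, 0.00477 without Ascl1-single replicate 1, 0.0244 without double-positive replicate 3 and 0.0156 without double-positive replicate 4) and the immediate early list (0.0212, against 0.273 without) were called. With the block and an estimated correlation together neither was (0.132 and 0.348).

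**Figure D3:**
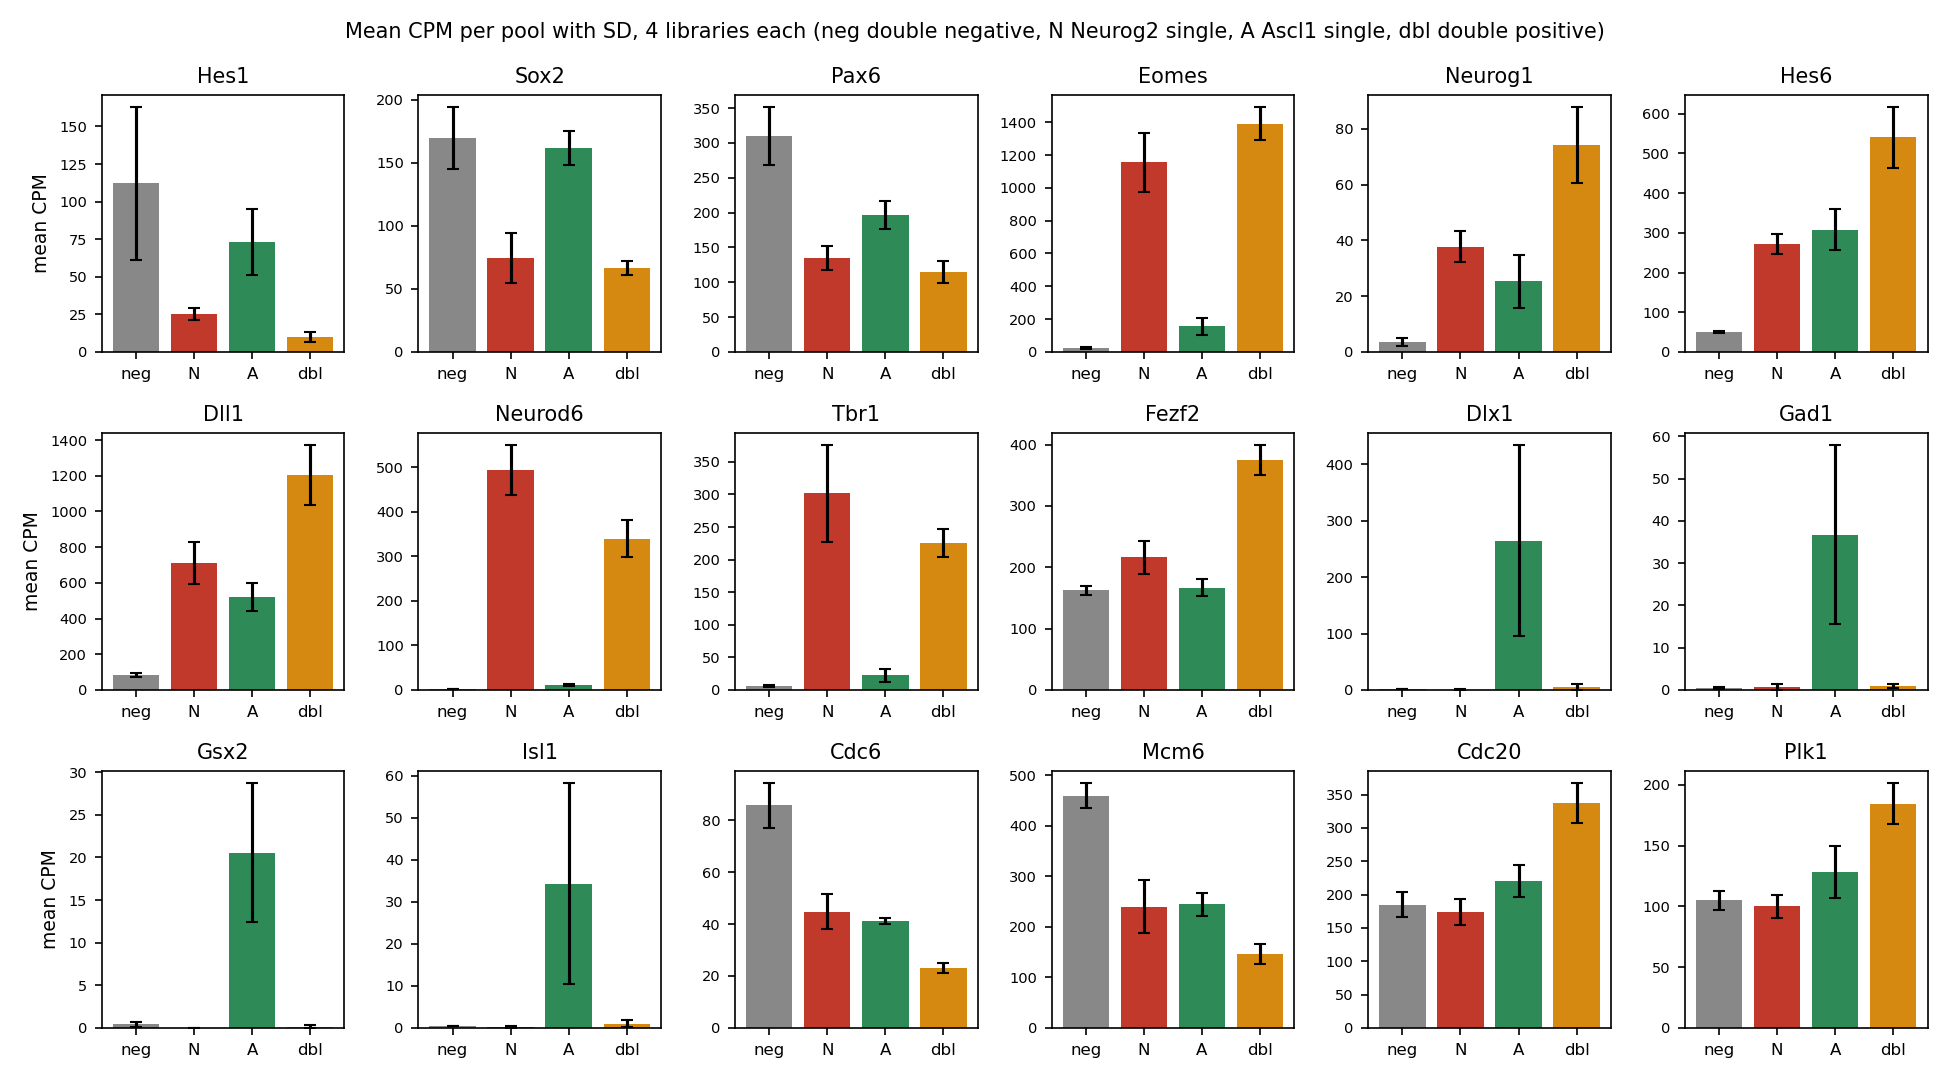
Mean CPM with SD (whiskers, 4 libraries per pool) of 18 genes of the lists in the double-negative (neg), Neurog2-single (N), Ascl1-single (A) and double-positive (dbl) pools, each panel with its own linear axis from 0. Eomes averaged 25.6, 1155, 155 and 1391 CPM and Dlx1 averaged 1.29, 0.498, 265 and 5.17 CPM in that order, while Cdc20 and Plk1 were highest and Cdc6 lowest in the double-positive pool.

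List levels per library, as the mean log2 CPM of the members, ordered the pools differently for each list. The exact permutations took libraries as unpaired, though replicate numbers pair some pools. With pairs kept, no exact permutation of 4 against 4 libraries could pass 0.05. The intermediate progenitor level was 3.93 ± 0.12 (SD, n = 4) in the double-negative, 5.97 ± 0.25 in the Ascl1-single, 7.68 ± 0.13 in the Neurog2-single and 8.06 ± 0.09 in the double-positive pool, and all 6 differences between pools reached the smallest two-sided exact permutation p of 4 against 4 libraries (0.0286, and 0.0286 adjusted over the 6 comparisons). The glutamatergic level was 3.81 ± 0.05, 4.72 ± 0.05, 6.61 ± 0.18 and 6.46 ± 0.11 in the same order, with no difference past the threshold between the Neurog2-single and double-positive pools (exact permutation p = 0.286). The GABAergic level was 4.58 ± 0.68 in the Ascl1-single pool and 0.11 ± 0.25, -0.24 ± 0.14 and 0.66 ± 0.58 in the double-negative, Neurog2-single and double-positive pools. The Ascl1-single level exceeded each of the others (exact permutation p = 0.0286, adjusted 0.0429). The S phase level was 7.48 ± 0.06 in the double-negative, 6.76 ± 0.27 in the Neurog2-single, 6.76 ± 0.13 in the Ascl1-single and 6.35 ± 0.07 in the double-positive pool. The G2 and M phase level was 7.49 ± 0.12, 7.28 ± 0.20, 7.54 ± 0.06 and 7.89 ± 0.02, highest in the double-positive pool (exact permutation p = 0.0286 against each other pool, adjusted 0.0429). By camera its calls against the Ascl1-single (adjusted p = 0.000102) and double-negative pools (0.000869) were lost with an estimated correlation (0.414 and 0.616). The S phase level of the double-positive pool was below that of the Neurog2-single pool by -0.41 (exact permutation p = 0.0286), and stayed at -0.44 to -0.39 without any 1 double-positive library. With 3 against 4 libraries only the most extreme of 35 splits can pass, and the exact permutation p was then 0.0571 (without replicate 3 or 4) or 0.0857 (without replicate 1 or 2). With the median over members the difference was -0.26 (exact permutation p = 0.0857).

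**Figure D4:**
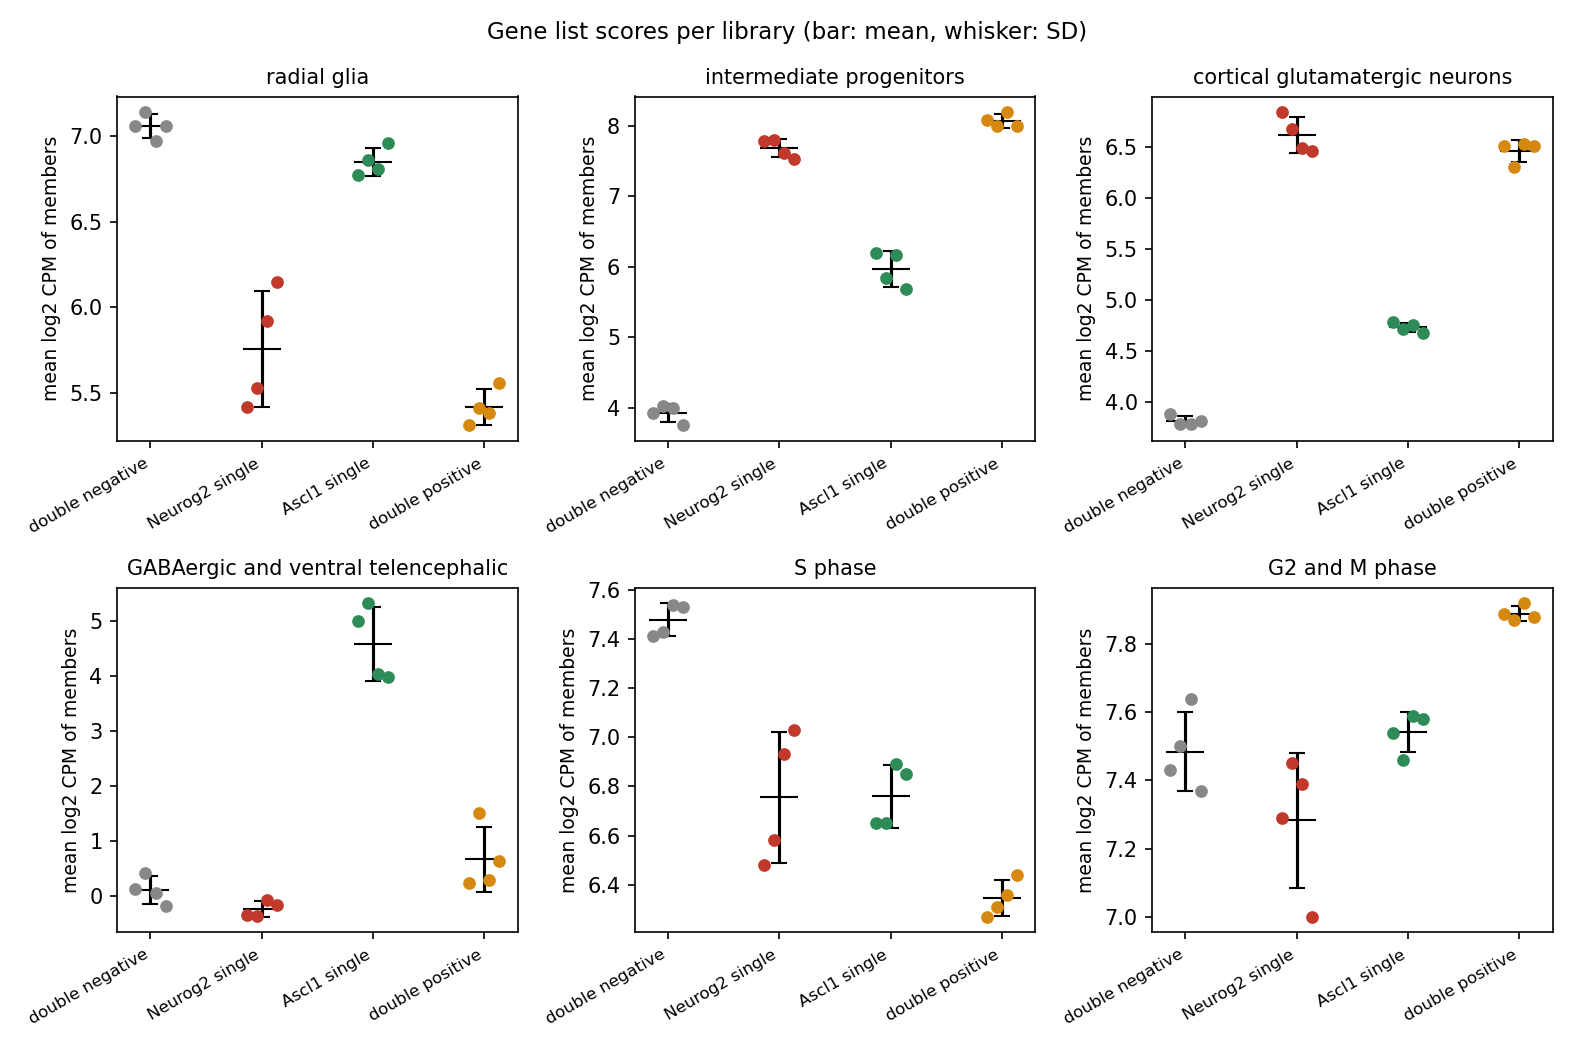
Mean log2 CPM of the tested members of 6 gene lists in each library, by pool, with points for libraries, bars for means and whiskers for SD; the axes do not start at 0. The G2 and M phase level averaged 7.89 in the double-positive pool and 7.28 to 7.54 in the others, and the GABAergic level averaged 4.58 in the Ascl1-single pool and at most 0.66 in the others.

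The marker interaction asked where the difference that goes with GFP was not the same with and without mCherry. It was called in 1999 genes by edgeR's quasi-likelihood test, of which 1430 were below 0, meaning that the double-positive pool lay below the sum of the single-marker log2 differences, and 569 above. The split was 1815 below and 1080 above with the replicate number as a block, 1280 and 323 with no filter, and 1627 and 386 with library size alone. Below 0 were 17 of 20 pan-neuronal genes, such as Tubb3 (-2.13 ± 0.21), 16 of 19 intermediate progenitor genes, such as Nhlh1 (-3.24 ± 0.29), and 16 of 17 Neurog2 target genes, such as Neurod1 (-3.10 ± 0.25), which rose with either marker. So were 11 of 15 Cajal-Retzius genes, such as Ebf2 (-3.78 ± 0.39), 7 of 11 cell cycle exit genes, such as Cdkn1c (-4.14 ± 0.38), and 10 of 20 GABAergic genes, such as Gad1 (-5.83 ± 0.85). Above 0 were 17 of 25 G2 and M phase genes, such as Aurka (0.71 ± 0.15) and Cdc20 (0.70 ± 0.15), and against their lists Fezf2 (0.75 ± 0.13), Tfap2c (1.04 ± 0.23), Emx2 (0.77 ± 0.16), Arx (0.74 ± 0.16) and Cdkn2c (0.67 ± 0.21). The interaction with the smallest adjusted p was below 0 for Olfm1 (-1.82 ± 0.13), Svop (-3.47 ± 0.24), Aplp1 (-1.93 ± 0.14) and the G protein regulator gene Rgs16 (-4.06 ± 0.29), each at adjusted p = 3.83e-07 by edgeR's quasi-likelihood test. It was above 0 for the heparan sulfate proteoglycan gene Gpc4 (1.39 ± 0.13), Tmc7 (1.5 ± 0.15), the Notch effector gene Hey1 (1.68 ± 0.19) and Mpped2 (1.64 ± 0.20). Rgs16 averaged 6.46, 126, 171 and 199 CPM in the double-negative, Neurog2-single, Ascl1-single and double-positive pools, and Hey1 128, 111, 49.3 and 137 CPM. By camera the pan-neuronal (adjusted p = 2.81e-35), intermediate progenitor, Neurog2 target, Cajal-Retzius and cell cycle exit calls held with an estimated correlation. The G2 and M phase call (adjusted p = 0.0804 with an estimated correlation, 3.52e-17 to 1.12e-11 over the other alternatives) and the GABAergic call (0.0676, others 6.45e-11 to 1.01e-07) did not, though the GABAergic list was called with the replicate block and an estimated correlation together (0.0347). Adjusted over the list alone, 21 G2 and M phase, 18 pan-neuronal, 17 Neurog2 target and 17 intermediate progenitor genes passed in these directions, as did 13 GABAergic genes. Erythroid genes were also called below 0 as a list (median -2.98, camera adjusted p = 5.36e-05), with 2 of 12 members called, such as Alas2 (-3.02 ± 0.61), and 4 when adjusted over the list alone, but not with an estimated correlation (0.208, others 3.96e-07 to 0.000319).

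The 3 comparisons against the double-negative pool shared genes. The Neurog2-single and double-positive pools shared 2798 higher and 2812 lower genes, with 16 called in opposite directions, where independent lists of these sizes would share 663 and 694. The Neurog2-single and Ascl1-single pools shared 1417 higher and 1238 lower with 260 opposite (447 and 337 for independent lists), and the Ascl1-single and double-positive pools 1563 and 1354 with 266 opposite (508 and 395). These comparisons use the same 4 control libraries, so part of each overlap comes from them. With the controls split 2 and 2, the Neurog2-single and double-positive pools shared 2043 to 2090 higher and 1946 to 1966 lower genes over 6 splits, the Neurog2-single and Ascl1-single pools 880 to 978 and 671 to 722, and the Ascl1-single and double-positive pools 974 to 1069 and 759 to 838. In 20 simulations all 16 libraries, the controls included, were drawn from the double-negative means. No call was shared, but unchanged groups hold few calls to share, so this cannot size the part from the controls. The simulated log2 differences still correlated at 0.493 to 0.498, with a covariance of 0.0709 to 0.0713. The observed covariance across genes was 1.05 for the Neurog2-single and double-positive pools (correlation 0.873), 0.546 for the Ascl1-single and double-positive pools (0.545) and 0.441 for the single-marker pools (0.496). Genes are not independent replicates in these figures.

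Lists of other cell types and of RNA quality were also compared. Against the double-negative pool, the median log2 difference of endothelial genes was -0.20 in the Neurog2-single, 0.31 in the Ascl1-single and -0.28 in the double-positive pool, and camera gave adjusted p = 0.844, 0.738 and 0.818. That of microglial and macrophage genes was -0.32, 0.25 and -0.22 (adjusted p = 0.991, 0.938 and 0.925), and that of mesenchymal, meningeal and pericyte genes -0.29, 0.52 and -0.40 (0.633, 0.938 and 0.693), with Prrx1 called lower in the Neurog2-single (-1.67 ± 0.22) and double-positive pools (-2.26 ± 0.23). Embryo sex genes had medians of -0.04, -0.18 and -0.02 (0.982, 0.718 and 0.868). Heat shock genes had medians of -0.27, -0.30 and -0.07, camera gave adjusted p = 0.289, 0.0548 and 0.649, and the chaperone gene Hspd1 was called lower in all 3 pools (-0.75 ± 0.08, -0.69 ± 0.08 and -0.83 ± 0.08). In the Ascl1-single pool this list was called with the replicate number as a block (0.0374) and without double-negative replicate 1 (0.0488), 2 (0.0466) or 4 (0.0438), but not with the block and an estimated correlation together (0.327). Mitochondrially encoded genes took 2.03% to 3.95% of the counts of each library and had medians of -0.34, -0.17 and -0.20 (0.0597, 0.271 and 0.570). In the Neurog2-single pool that list was called with the replicate number as a block (0.0434), with library size alone (0.0419) and without double-negative replicate 1 (0.0357) or 2 (0.00159) or Neurog2-single replicate 3 (0.0215), and in the Ascl1-single pool without double-negative replicate 2 (0.0169). With the block and an estimated correlation together it was not called in the Neurog2-single pool (0.721). Between the double-positive and Neurog2-single pools the mitochondrial list was called higher (median 0.15, camera adjusted p = 0.0196), but not with an estimated correlation (0.732, others 0.000675 to 0.185) or without Neurog2-single replicate 2 (0.185) or 4 (0.0639) or double-positive replicate 1 (0.0527). In the interaction it was called above 0 (median 0.32, adjusted p = 0.0127), but not with an estimated correlation (0.531, others 5.52e-05 to 0.111) or without double-negative replicate 3 (0.111) or Ascl1-single replicate 4 (0.0594). Heat shock genes were also called above 0 in the interaction (median 0.38, adjusted p = 0.00507), and surface ectoderm genes lower in the double-positive than in the Ascl1-single pool (median -1.11, adjusted p = 0.0125). With an estimated correlation these were not called (0.199, others 0.00318 to 0.0285, and 0.0847, others 0.00756 to 0.0298). Against the double-negative pool, surface ectoderm genes had medians of -0.67 in the Neurog2-single, 0.94 in the Ascl1-single and -0.97 in the double-positive pool, and camera gave adjusted p = 0.289, 0.0620 and 0.570. In the Ascl1-single pool the list was called without double-negative replicate 1 (0.0488) or Ascl1-single replicate 2 (0.0495). Its list level differed from that of the double-negative pool by -0.68, 0.89 and -0.57 (exact permutation p = 0.0286, 0.0286 and 0.0571, adjusted 0.0429, 0.0429 and 0.0685).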

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

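The tests of ventral cells and of scaling, the test of endothelial genes, the test of a mixed double-positive pool and the permutations of the interaction were chosen after the results were seen. In 16 of 296 sets of 4 libraries examined, 1 library lay far from the other 3 (by a Dixon test of the gap over the range), where chance gives about 15. By CPM these were, with the range of the other 3 libraries, Fut4 in Ascl1-single replicate 4 (0.545, others 0.191 to 0.210), Neurod6 in double-positive replicate 2 (277, 358 to 362), Six3os1 in double-positive replicate 2 (22.4, 3.26 to 6.47), Isl1 in Neurog2-single replicate 3 (0.627, 0.137 to 0.169), Hey2 in double-negative replicate 2 (23.6, 31.3 to 31.6), Tgfb2 in double-positive replicate 1 (12.8, 16.5 to 17.1), Six3 in Neurog2-single replicate 1 (0.296, 0.548 to 0.574) and C1qtnf1 in Neurog2-single replicate 2 (5.48, 2.08 to 2.13). Also far from the others were Shox2 in Ascl1-single replicate 2 (1.34, 0.276 to 0.383) and in double-positive replicate 3 (1.15, 0 to 0.103), Nkx2-1 in Neurog2-single replicate 3 (0.627, the others at 0), Dlx2 in double-positive replicate 2 (2.42, 0.802 to 1.08), Svop in Ascl1-single replicate 2 (6.76, 4.70 to 4.99), Aplp1 in Neurog2-single replicate 4 (151, others at most 129) and Rgs16 in double-positive replicate 3 (227, 188 to 190). The glutamatergic list level of double-positive replicate 2 was 6.30, against 6.51 to 6.53 in the other 3.

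The difference that goes with GFP was not the same with and without mCherry in 1999 genes, by the interaction test of edgeR. The genes with the smallest adjusted p were Olfm1 (-1.82), Svop (-3.47), Aplp1 (-1.93) and Rgs16 (-4.06) below 0, and Gpc4 (1.39), Tmc7 (1.5), Hey1 (1.68) and Mpped2 (1.64) above 0, as log2.

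GABAergic and ventral genes were higher in the Ascl1-single pool. With scaling by library size alone 18 members were called, as many as with TMM scaling. The TMM factors averaged 1.05 in this pool and 1.02 in the double-negative pool. That gap is too small to make or remove log2 differences such as that of Dlx1 (7.65), so the count of calls is no separate support. Ventral cells carried into the dissected tissue would lower dorsal progenitor genes, and the median log2 difference of 4 such genes was -0.58, with Emx2 (-0.75 ± 0.11) and Dmrt3 (-1.08 ± 0.28) called lower, while Emx1 (-0.31 ± 0.27) and Dmrta2 (-0.40 ± 0.19) were not. Cells from ventral telencephalon and ventral genes switched on in dorsal Ascl1-positive cells cannot be told apart, since both may lower dorsal genes and the libraries hold no mark of where a cell arose. No test of the second explanation was made.

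Erythroid genes were higher in the Neurog2-single pool, with a median of 4.54 over 7 globin genes and 3.56 over the 5 other members. Red blood cells or their RNA in that pool are a candidate explanation, tested on 18 erythroid genes outside the list that were written down before their values were seen. The 10 with enough counts had a median of 2.81, with 7 called higher, such as Spta1 (3.86 ± 0.90), Kel (4.15 ± 0.99) and Epb42 (2.89 ± 0.47). The other 3, Slc25a37 (-0.55 ± 0.16), Tspan33 (-0.55 ± 0.16) and Gypc (-1.11 ± 0.18), were called lower, and averaged 52.5, 14.1 and 15.1 CPM in the double-negative pool against at most 1.28 CPM for the 7. Carry-over of non-neural cells of every kind was argued against by endothelial genes, with a median of -0.20. The sort for CD15 would be expected to remove red cells, and no biological explanation was tested.

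Interaction calls below 0 were also weighed against arithmetic and mixing. Differences that add on the linear scale would put the double-positive pool at the linear sum, but the median ratio to it over 1430 genes was 0.53 (quartiles 0.282 and 0.714), and 1217 genes lay below it by over 2 standard errors. The genes were chosen for an interaction below 0 in these same libraries, which itself pulls the ratio down. These values are therefore not independent evidence against linear addition. A double-positive pool that only mixes cells of the other 3 pools, in their average makeup, was argued against by 330 genes called beyond the range of all 3, 123 higher and 207 lower. A mix of selected cells of those pools could lie beyond their means, so it is not argued against. No biological explanation was tested.

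Other splits of the same libraries argue against chance for all 6 comparisons, where 1 split, the real one, gave as many calls. Over 35 splits the highest other gave 0 calls by edgeR for each comparison with the double-negative pool (6519, 4351 and 7532 real), 1 for the double-positive against the Neurog2-single pool (603 real), 1 against the Ascl1-single pool (5784 real) and 78 for the Ascl1-single against the Neurog2-single pool (4945 real). In the last 2, those of the other splits that part every pair gave 0 calls, and the rest keep some pairs together. For the interaction, residuals of the fit without it were permuted within replicate numbers, which keeps the single-marker differences. By limma-trend on log2 CPM, 2 of 100 orders gave as many calls, the real one (2067) and another (2503), which also argues against chance. That other order left all 16 libraries on their own side of the interaction, so it holds the real pattern again, and the next highest gave 586 calls.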

How the results depend on the processing

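None of the checked pairs of named gene and comparison, list tests or list levels that was called reversed under an alternative. The pairs were those of the sort genes, the genes furthest up or down, the interaction genes and up to 4 called members per list. Other named genes were not all checked. Which direction held more calls did turn where the split was near even: Ascl1-single against Neurog2-single from 2464 higher and 2481 lower to 3291 and 1789 with library size alone, and with DESeq2 Neurog2-single against double-negative to 3581 and 3465 and double-positive against double-negative to 4082 and 3972. Of 9144 values of 542 pairs of named gene and comparison, 8813 stayed as in the main fit, called or not, and 331 lost a call. The count of double-positive against Neurog2-single calls (603) moved furthest, to 1121 with DESeq2, 381 with only the 2 pools, 1076 with the replicate block, and 330 (without double-positive replicate 1) to 663 (without double-positive replicate 4) with 1 library left out; the cause was not tested. With control libraries split 2 and 2 (mean of 6 splits), calls shared by the Neurog2-single and Ascl1-single pools went from 2655 to 1614 and by the Ascl1-single and double-positive pools from 2917 to 1821, with fewer controls per test. Other counts stayed within 1.5 times, and without 1 library ranged 5478 to 6495 (Neurog2-single against double-negative), 3474 to 4040 (Ascl1-single against double-negative), 6897 to 7343 (double-positive against double-negative), 5018 to 5602 (double-positive against Ascl1-single), 3980 to 5047 (Ascl1-single against Neurog2-single) and 1560 to 2054 (interaction). Scaling by library size alone moved the median log2 difference of all genes from -0.001 to -0.136 (double-positive against Ascl1-single) and from 0.003 to 0.113 (Ascl1-single against Neurog2-single), and by under 0.1 elsewhere. Of 182 list tests 88 were called, and 34 of these were lost with an estimated correlation. Of the 34, 27 were kept with the replicate block, with library size alone and without any 1 library. DESeq2, other filters and limma-trend were not tried on lists. With the block and an estimated correlation together 38 of the 88 were lost, some of which had held with an estimated correlation alone. Of the 34, that setting called only S phase between the double-positive and double-negative pools and the GABAergic list in the interaction. The replicate numbers did not pair the double-positive with the double-negative (correlations 0.06 to 0.26) or Neurog2-single libraries (0.08 to 0.30), though all 16 libraries correlated best with their own number. The block called Cajal-Retzius (camera adjusted p = 0.00107, against 0.0510) and folding genes (0.0346, against 0.0821) there, and immediate early genes in the interaction (0.0328, against 0.129), all lost with the block and an estimated correlation together (0.0746, 0.219 and 0.353); besides those in the report it changed no other list call, and 1 named gene call. What depth limits was not tested. Fut4, at few counts, lost its call between the Neurog2-single and double-negative pools with no filter (0.0640) and without each of 4 libraries (double-negative replicate 1, 0.0732; replicate 4, 0.0701; Neurog2-single replicate 2, 0.0588; replicate 3, 0.0800; edgeR adjusted p).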

Other observations

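The test of neighbouring diencephalon was chosen before its values were seen. Most of the 330 genes that stood in the double-positive pool beyond all 3 other pools were in none of the lists, and the genes below were chosen after their values were seen. Higher than in each other pool were Dll1, a Notch ligand, Mfng, which modifies Notch, Hes6, which antagonises Hes1, and Gadd45g, with averages of 84.0, 711, 521 and 1205 CPM for Dll1 in the double-negative, Neurog2-single, Ascl1-single and double-positive pools. Fezf2, of the glutamatergic list, averaged 162, 216, 167 and 375 CPM. Also higher were 11 G2 and M phase genes, among them Ube2c and Plk1. Lower than in each other pool were 8 S phase genes, among them Cdc6 and Mcm6, the Notch ligand gene Jag1, Ptch1, and Nr2e1, a factor of neural stem cells.

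Shox2, Olig3 and Tcf7l2, which are transcribed in the thalamus and other parts of the diencephalon, were higher in the Neurog2-single than in the double-positive pool. In the double-negative, Neurog2-single, Ascl1-single and double-positive pools Shox2 averaged 0.950, 23.6, 0.595 and 0.336 CPM, Olig3 4.08, 19.4, 3.93 and 0.600 CPM, and Tcf7l2 23.1, 64.7, 43.6 and 5.77 CPM. Diencephalic cells in the Neurog2-single pool alone would not explain why Olig3 and Tcf7l2 were lower in the double-positive than in the double-negative pool (-2.76 ± 0.71 and -2 ± 0.37) and in the Ascl1-single pool (-2.70 ± 0.71 and -2.92 ± 0.38). For the rise in the Neurog2-single pool, if cells from neighbouring diencephalon lay behind it, other diencephalic genes would be higher too, and 2 of 12 tested were called, Gbx2 (-6.30 ± 0.91 in the double-positive over the Neurog2-single pool) and Tal1 (-3.64 ± 0.64), which is also an erythroid and endothelial gene. That is too few to tell, so diencephalic cells may or may not be present in that pool.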
